A study of Medicago truncatula with 4 samples.

How the data were processed

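Small RNA libraries from Medicago truncatula leaves were compared. All 4 libraries came from total RNA treated with TAP (tobacco acid pyrophosphatase, which turns capped or triphosphate 5′ ends into monophosphates that can be ligated), per the labels. Of these, 2 were built with HD adapters (high definition adapters, which carry degenerate bases at the ligating ends) and 2 with standard Illumina adapters. The groups follow the adapter label of each sample. The library protocol text in the labels names standard adapters for all 4 samples, so the label and the protocol text differ. The longest read was 33 nt in both HD libraries and 41 nt in both standard libraries. The labels number the replicates but do not say whether they came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

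The deposited files list each distinct read sequence with its whole-number read count, as the authors made them, with no scaling between libraries. Adapters had been removed and reads collapsed before deposit, as seen from the files. The trimming tool, its filters and any genome are not given in the sources used here. No genome was used, so no positions are given and the planned share of genome-matched reads was not computed. The files hold 46640691 reads of 13104749 distinct sequences. Total reads were 12131240 and 8967736 in HD replicates 1 and 2, and 13560223 and 11981492 in standard replicates 1 and 2. At these depths, 1 read was worth between 0.0820 and 0.122 CPM (reads per 1000000 reads of 18 to 30 nt). A group with no reads of a sequence was set to a floor of 3 counts over the group, which was 0.153 CPM in HD and 0.130 CPM in standard. Reads have no molecular identifiers, so these floors cover counting error only.

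The sequences and counts were split and joined with pandas 2.3.3 in Python 3.11.15, and reads of 18 to 30 nt were kept. Sequences were tested when they reached the CPM worth 10 reads at the median library total in at least 2 libraries and summed to at least 15 reads. Scaling was by the trimmed mean of M-values, trimming 30% of log ratios and 5% of intensities at each end. The test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1) with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment at 0.05 over all sequences and fragments in the fit. Fold changes are HD minus standard on that log2 scale, which understates changes of rare sequences. The test chosen at first was a count model, with a second count model beside it. The counts are stored in text cells together with their sequence and were not accepted as the numeric count table those models were reserved for, although the values are counts. The limma test on log2 values, set down in the design for normalized values, was used in their place, and neither count model was run.

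Counts were simulated for the 73259 tested sequences with the libraries' own sizes and 1 common spread estimated from the replicates (dispersion 0.0356). Known folds were given to 200 of the more frequent sequences. The fit called 10 of 67 sequences changed 2-fold, 60 of 67 changed 4-fold and all 66 changed 16-fold, and made 7 false calls among 73059 unchanged sequences. Nearly all simulated sequences were unchanged, while 63393 of 73259 were called in the real libraries. The simulation therefore cannot show how many of those calls are false, or whether the scaling holds where most sequences differ.

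The choice of tests, lists, the rule for named items and the alternatives were made before the data were examined, except where said otherwise. Mature sequences of conserved plant miRNAs and tasiRNAs and the 5′ starts of tRNAs, U-class RNAs and ribosomal RNAs were listed from general knowledge. The miRNAs were grouped by their known targets: development, silencing machinery, nutrient and copper stress, and triggers of phased siRNAs from NLR resistance genes. Listed miRNAs were matched exactly, and 5′ starts were summed over all reads that began with them. The rule for named items takes every listed item tested, with full values for the few largest changes and the most abundant of each list. It also takes the 5 most HD-high and 5 most standard-high sequences that passed the test, averaged at least 50 CPM and did not overlap between groups, and the 5 most abundant sequences. Lists were set against all other sequences with camera, with a preset correlation of 0.01 and with an estimated correlation. The estimated setting also tests with only the few residual degrees of freedom of the libraries. A call lost with it therefore need not mean that the members of a set are correlated.

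Shares of reads by length and end base, and numbers of distinct sequences after drawing 8172741 reads without replacement, were compared by exact permutation tests over the 6 splits of the libraries. The smallest 2-sided p of that design is 0.3333, so none of these tests can pass 0.05. The alternatives were 2 other scalings, 2 other filters, reads of 20 to 24 nt, the replicate number as a block, each library left out, end variants of listed miRNAs summed, distinct sequences in place of reads, shares without the 10 most abundant sequences or without sequences read once, all lengths and other draws. Chosen after seeing the data were voom weights, a pseudocount of 0.1, and leaving out reads that hold CAGTCCGACGATC, the 3′ part of the Illumina 5′ adapter. The counts of T-ended forms, the end triplets, the 5.8S rRNA reads and all sequences said below to be picked afterwards were also chosen after seeing the data. End forms were counted for listed miRNAs with at least 10 CPM of end variants in each library. T-ended forms were the listed sequence, whole or up to 3 bases shorter, with 1 to 4 added T that it does not hold, as a share of reads that begin with the sequence less its last 3 bases, where each library had at least 20 such reads. Forms equal to another listed miRNA were not counted as T-ended. Folding energies came from ViennaRNA 2.7.2, and permutations and correlations from numpy 2.4.6 and scipy 1.17.1.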

Results

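Leaf small RNAs of Medicago truncatula were sequenced after TAP treatment in 2 libraries with HD adapters and 2 with standard Illumina adapters, to set the small RNA populations from each adapter type side by side. Reads of 18 to 30 nt numbered 11416856 and 8172741 in HD replicates 1 and 2, and 12191542 and 10891011 in standard replicates 1 and 2. Values are means ± SD of 2 libraries unless stated. All differences below are between adapters.

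The size class of 24 nt, the length of heterochromatic siRNAs in plants, was the main class in HD libraries and not in standard libraries. It held 47.2 ± 0.479% of reads in HD and 12.8 ± 0.486% in standard libraries, a ratio of 3.69. The 21 nt class, the length of most plant miRNAs, held 15.3 ± 0.392% in HD and 18.7 ± 0.213% in standard. Reads of 22 nt (6.48 ± 0.153% and 9.23 ± 0.0751%), 23 nt (8.52 ± 0.285% and 12.5 ± 0.0275%) and 26 nt (1.52 ± 0.0323% and 6.18 ± 0.192%) were also less frequent in HD. Each of these differences exceeded the spread between replicates, and each gave p = 0.3333, the smallest value the exact permutation test allows. The 21 nt difference, −3.41 percentage points, shrank to −0.700 points without the 10 most abundant sequences and turned to 0.0686 points without sequences read once in a library.

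**Figure D1:**
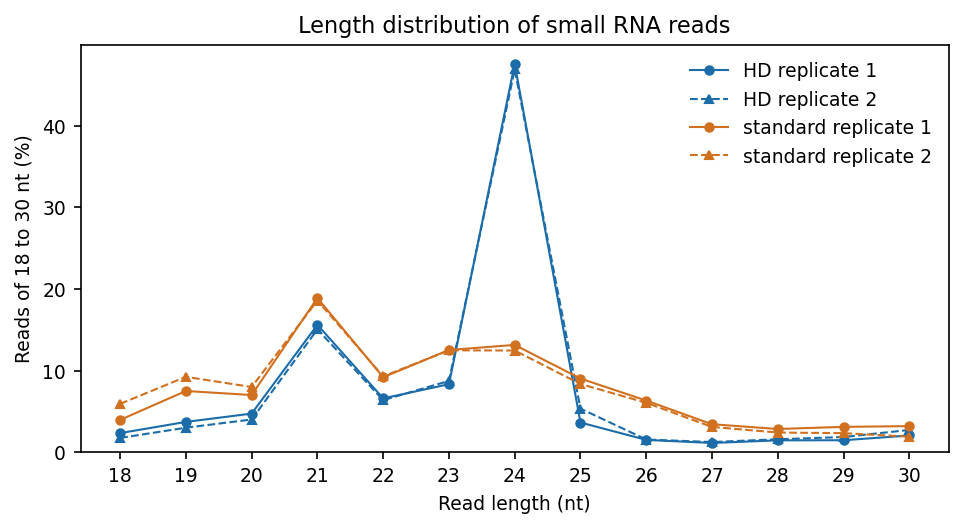
Share of reads (%) of each length from 18 to 30 nt, with a line for each library. Both HD libraries peak at 24 nt (47.6% and 46.9%), where the standard libraries hold 13.1% and 12.5%.

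First bases differed within the miRNA size class. Reads of 21 nt began with T, the typical first base of plant miRNAs, in 64.0 ± 1.42% of cases in HD and 29.9 ± 0.991% in standard libraries, and with A in 13.3 ± 0.221% and 42.9 ± 0.570%. Within 22 nt, T was first in 48.8 ± 0.524% and 25.7 ± 0.703%, and G in 16.7 ± 0.225% and 32.3 ± 0.503%. Within 24 nt, A was first in 41.5 ± 0.848% of HD reads and 32.7 ± 0.355% of standard reads. At the 3′ end, C was last in 28.4 ± 1.41% and 37.1 ± 0.133% of reads of all lengths, and G in 18.6 ± 0.669% and 12.7 ± 0.204%. A was last in 31.1 ± 0.163% and 27.9 ± 0.685%. Over all lengths, T was first in 32.2 ± 0.304% and 26.5 ± 1.14% of reads and A in 31.8 ± 0.725% and 29.6 ± 0.224%. All of these had p = 0.3333 in the exact permutation test, the smallest it allows. Without the 10 most abundant sequences, the difference within 21 nt shrank from 34.2 to 10.95 percentage points for T and from −29.6 to −3.70 points for A, that for G within 22 nt from −15.5 to −9.00 points, and that for T over all lengths to 0.551 points. Over distinct sequences the differences were 9.50 points for T and −0.987 for A within 21 nt, 5.92 for T and −6.78 for G within 22 nt, 5.58 for A within 24 nt, −2.55 for last base C and −0.578 for T over all lengths, and A over all lengths turned to −0.984 points without sequences read once.

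Ribosomal and adapter-derived reads were more frequent in standard libraries. Reads holding ACTCTCGGCAACGG, a conserved stretch near the 5′ end of plant 5.8S rRNA picked after the data were seen, made up 0.734 ± 0.0512% of HD and 8.04 ± 0.184% of standard reads. The 5.8S fragment AGAATGACTCTCGGCAACGGA had the highest mean CPM over the 4 libraries, through the standard libraries, at 1897 ± 153 CPM in HD and 57740 ± 2198 CPM in standard (log2 fold change −4.59, SE 0.39, adjusted p = 0.000465). It begins with A and is 21 nt long, and its log2 fold change was −3.49 with a stricter filter. Reads that hold the 3′ part of the Illumina 5′ adapter anywhere made up 1.13 ± 0.174% of HD and 4.67 ± 0.457% of standard reads, and those that end with it 0.0102 ± 0.00246% and 4.35 ± 0.424%. As HD adapters carry degenerate bases at their ligating ends, the contrast in reads that end with it may follow from adapter design alone.

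HD libraries held more distinct read sequences. After each library was drawn down to 8172741 reads, 3841681 ± 29142 distinct sequences were found in HD and 2303142 ± 56644 in standard libraries, a ratio of 1.67. The 10 most abundant sequences of a library took 8.92 ± 0.156% of HD and 13.9 ± 0.697% of standard reads, and the 100 most abundant took 17.8 ± 0.253% and 31.9 ± 1.22%. Both measures gave p = 0.3333, the smallest the exact permutation test allows. The ratio was 1.22 when only sequences with at least 2 reads after the draw were counted. Before the draw, 81.2% and 83.5% of distinct sequences were read once in HD replicates 1 and 2. In standard replicates 1 and 2 these shares were 72.2% and 74.0%. Without a genome, it was not tested whether sequences read once are small RNAs of the plant.

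**Figure D2:**
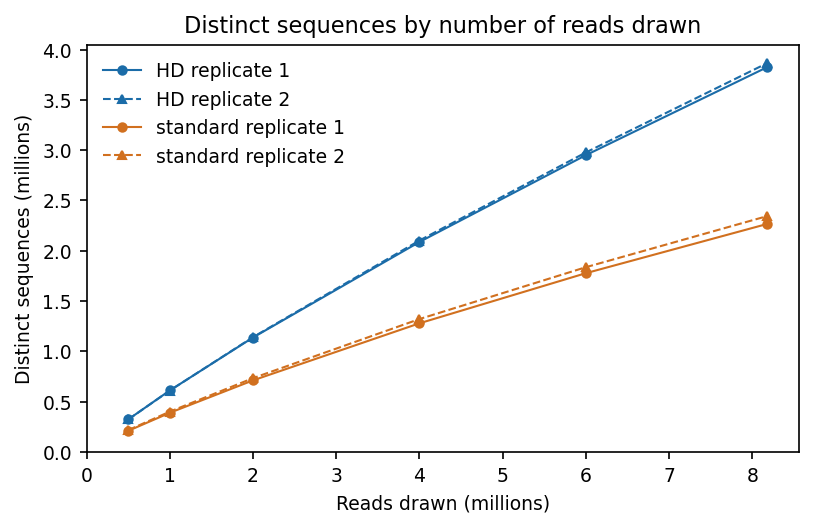
Distinct sequences against the number of reads drawn from each library, both in units of 1000000, from a separate random draw. At 8172741 reads the HD libraries reach 3822298 and 3862287 sequences and the standard libraries 2265462 and 2343462.

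Of 73259 sequences tested, 63393 differed between the adapters, 34330 higher in HD and 29063 higher in standard libraries (limma, adjusted p under 0.05, 2-sided, with 63892 at an unadjusted p under 0.05). The sequence with the largest rise in HD was the 19 nt AGCCTATGATGATAAAACA, with 84933 and 46836 reads in the HD libraries and 0 and 1 in the standard libraries (log2 fold change 12.79, SE 0.32, adjusted p = 0.000448). AGATCCATTGTAGTCTTGATATTATATA followed, at 2561 ± 330 CPM in HD and 0.251 ± 0.225 CPM in standard. The other 3 of the 5 share the 3′ end of AGCTCAACGAGAACAGAAATCT. That sequence was at 1070 ± 78.5 CPM in HD and had no reads in either standard library, at least 8231-fold higher in HD. ATGAGCTCAACGAGAACAGAAATCT was at 1482 ± 331 CPM and 0.0820 ± 0.116 CPM, and GAGCTCAACGAGAACAGAAATCT at 1262 ± 167 CPM and 0.0410 ± 0.0580 CPM. By length, the median log2 fold change was 1.30 for 28661 sequences of 24 nt and 0.60 for 8421 of 21 nt, and it was below 0 for every other length, down to −1.10 at 26 nt. Fewer sequences passed in either direction with a library left out, where the fit has fewer degrees of freedom.

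All 5 sequences most raised in standard libraries ended in a part of the Illumina 5′ adapter. CAGAGTTCTACAGTCCGACGATC was at 10116 ± 142 CPM in standard and 1.23 ± 0.361 CPM in HD. TAGTTCTACAGTCCGACGATC, AGAGTTCTACAGTCCGACGATC and TCAGAGTTCTACAGTCCGACGATC were at 4899 ± 593, 7479 ± 332 and 624 ± 45.8 CPM in standard, and each was under 2 CPM in HD. TAGAGTTCTACAGTCCGACGATC had no reads in HD and was at least 9225-fold higher in standard libraries. HD adapters carry degenerate bases at the ligating ends, so pieces of them would be spread over other sequences. These folds may therefore follow from adapter design alone. Among the sequences most abundant over the 4 libraries, GGAATGTTGTCTGGCTCGAGG, the 5p arm of miR166, was at 5371 ± 1681 CPM in HD and 13865 ± 3149 CPM in standard (log2 fold change −1.05, adjusted p = 0.0871). CGGGGCGACATGGGACAAC fell by 2.22 on the log2 scale in HD (2138 ± 978 and 11928 ± 1271 CPM, adjusted p = 0.00937), a call lost without either standard library (−1.90 and −2.25). TTGACAGAAGATAGAGGGCAC was at 8143 ± 2551 and 4368 ± 1706 CPM (adjusted p = 0.0659). GGAATGTTGTCTGGCTCGAGG passed with library size scaling (−1.39), a looser filter (−1.38), 20 to 24 nt (−1.64) and the replicate number as a block, and turned to 0.050 with a stricter filter. TTGACAGAAGATAGAGGGCAC passed with median-of-ratios scaling (1.69), the stricter filter (2.35) and the block, and was 1.87 without standard replicate 1.

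Conserved miRNAs were mostly higher in HD libraries. Of 29 listed miRNAs tested, 25 were higher in HD, miR166 was higher in standard libraries, and miR157, miR168 and miR399a did not pass (limma, 26 past 0.05 over all sequences and 26 adjusted over the list alone). Their median log2 fold change was 3.14, or 3.20 with miR394, which had no reads in the standard libraries, set at its bound. The exact sequences of miR170, miR403, miR395a, miR2109, miR482, miR5213 and both listed tasiRNAs had no reads.

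Of 19 development miRNAs tested, 17 were higher in HD. By exact sequence, the largest rises were of miR172, which targets AP2-like transcription factors (310 ± 142 CPM in HD and 2.03 ± 0.267 CPM in standard, log2 fold change 6.88, SE 0.35, adjusted p = 0.000448), and of miR160, which targets auxin response factors (166 ± 47.7 and 1.15 ± 0.460 CPM, log2 fold change 6.51, SE 0.36, adjusted p = 0.000448). miR169d, which targets NF-YA subunits, rose by 5.09 on the log2 scale, miR319, which targets TCP factors, by 4.99, and miR164, which targets NAC factors, by 4.76. With end variants summed, these values were 4.29 for miR172, 3.50 for miR160, 2.63 for miR169d, 2.14 for miR319 and 2.64 for miR164, and miR167 (3.62 by exact sequence) had the largest, at 4.55. The listed miRNA most abundant in HD was miR159, a regulator of MYB factors, at 28507 ± 2281 CPM in HD and 2295 ± 20.5 CPM in standard (log2 fold change 3.97, SE 0.37, adjusted p = 0.000500), below miR166 and miR168 in both standard libraries. In standard replicates 1 and 2, miR159 was at 2310 and 2281 CPM and miR396a at 1795 and 3048 CPM. miR156, which targets SPL factors, was at 9345 ± 3086 and 1282 ± 426 CPM. miR394 had 16 and 19 reads in HD and none in standard, at least 14.3-fold higher in HD, while its summed end variants were at 92.5 ± 12.8 CPM in HD and 34.7 ± 5.89 CPM in standard. miR166, which targets class III homeodomain-leucine zipper genes, went the other way, at 1391 ± 323 CPM in HD and 6077 ± 634 CPM in standard (log2 fold change −1.80, SE 0.41, adjusted p = 0.00851). Calls were lost for miR166 without standard replicate 1 (−1.71) or 2 (−1.63) and with a stricter filter (−0.71), for miR156 without HD replicate 1 (2.77) or standard replicate 2 (2.93), for miR319 of 21 nt without HD replicate 2 (1.87), for miR390 without standard replicate 1 (3.65) or 2 (3.25), for miR394 without standard replicate 1 (1.62) or 2 (1.59), and for miR396b without HD replicate 1 (3.87) or 2 (3.45). Without HD replicate 1 and HD replicate 2, the values were 4.14 and 5.39 for miR164 and 2.68 and 4.09 for miR390. Calls for miR393 (0.54 to 0.88) and miR396a (1.10 to 1.74) were lost without any 1 library and with library size scaling (0.39 and 0.94) or for 20 to 24 nt (0.15 and 0.69), and for miR393 with a looser filter (0.39), while miR157 passed without standard replicate 1 (1.33), with median-of-ratios scaling (1.17) and with the replicate number as a block.

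Triggers of phased siRNAs from NLR resistance genes were higher in HD in 3 of 3 tested. miR2118 was at 2014 ± 604 CPM in HD and 29.8 ± 4.55 CPM in standard (log2 fold change 6.34, SE 0.40, adjusted p = 0.000448), miR1507 rose by 3.46 on the log2 scale, and miR1510 was at 36.8 ± 2.06 and 16.0 ± 4.52 CPM (adjusted p = 0.00480). With end variants summed, the log2 fold changes were 4.17 for miR2118, 2.33 for miR1507 and 1.28 for miR1510. Of 5 stress miRNAs, 4 were higher in HD. miR398a and miR398b, which target copper/zinc superoxide dismutases, rose by 4.08 and 3.14, and miR408, which targets copper proteins, by 2.71. With end variants summed, the values were 3.08 for miR398a, 2.64 for miR398b and 0.05 for miR408. miR397, a regulator of laccases, was at 1.41 ± 0.608 and 0.128 ± 0.0511 CPM. miR162, which targets Dicer mRNA, was at 308 ± 73.7 CPM in HD and 90.2 ± 3.35 CPM in standard (log2 fold change 2.08, SE 0.36, adjusted p = 0.00309). miR168, which targets ARGONAUTE mRNA, was at 6659 ± 1281 and 5083 ± 2309 CPM (log2 fold change 0.79, SE 0.51, adjusted p = 0.192). Calls were lost for miR1510 without HD replicate 1 (1.48) or 2 (1.54), for miR397 without standard replicate 1 (1.25) or 2 (1.14) and for miR398b without HD replicate 1 (3.08) or 2 (3.20), which was 3.86 without standard replicate 2, while miR168 (1.48 without standard replicate 1) passed with median-of-ratios scaling (1.23) and a stricter filter (1.89).

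**Figure D3:**
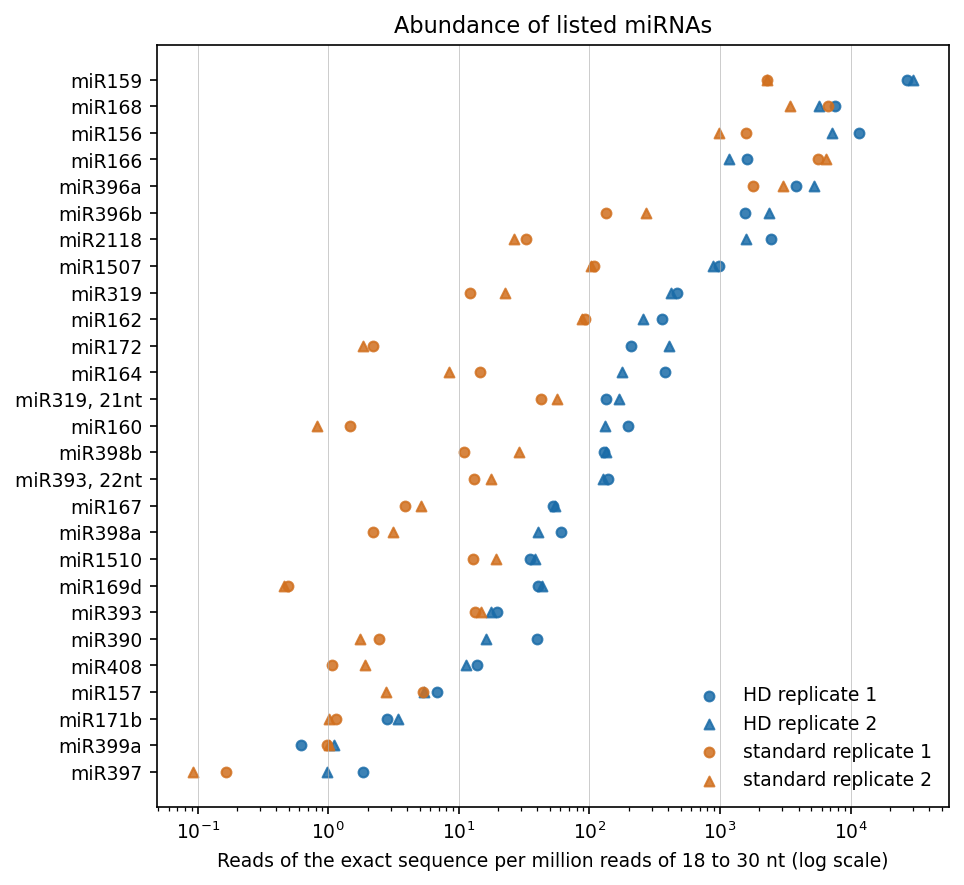
CPM (log scale) of 27 listed miRNAs read in all 4 libraries, by exact sequence, with a point for each library. HD points lie right of standard points for most, such as miR172 (310 and 2.03 CPM), while miR166 lies the other way (1391 and 6077 CPM).

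The same miRNAs ended differently in the HD and standard libraries. Among 24 listed miRNAs with enough reads, the exact listed form made up a larger share of all end variants in both HD libraries for 21, with medians of 60.4% and 63.7% in HD and 8.88% and 8.34% in standard libraries. The exact share was higher in both standard libraries for miR396a and miR167. End variants of miR169a and miR169d are the same reads, and so are those of miR396a and miR396b. Those of the listed lengths of miR393 and of miR319 are nearly the same. These counts are thus not of independent miRNAs, and the exact form of one such member lowers the exact share of the other. miR160 was 91.1 ± 0.579% exact in HD and 6.04 ± 1.94% in standard, miR2118 89.3 ± 0.499% and 19.3 ± 2.31%, and miR408 54.8 ± 3.20% and 5.21 ± 0.774%. Forms with added T were more frequent in both standard libraries for 22 of 23 miRNAs, with miR166 the exception. Of reads with the required start of miR393 of 22 nt, they made up 77.2 ± 1.85% in standard and 5.64 ± 0.0164% in HD. For miR169d these shares were 59.3 ± 1.64% and 0.313 ± 0.0867%. They rest on few reads, with 6 and 5 of the exact form in the standard libraries. Without a genome, T bases encoded in a precursor or in another family member cannot be separated from T bases added later. TCCAAAGGGATCGCATTGATTTT, a form of miR393 picked after the data were seen, was at 128 ± 1.29 CPM in standard and 0.586 ± 0.209 CPM in HD, while TCCAAAGGGATCGCATTGATCC was at 15.3 ± 3.24 and 133 ± 8.41 CPM.

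With all end variants summed, 28 of 35 listed small RNAs differed, 26 of them higher in HD, and the median log2 fold change was 2.14. Listed sequences with the same inner part, such as miR396a and miR396b, have the same sum. miR162, miR393 and miR408 no longer differed, at log2 fold changes of 0.06 (SE 0.37, adjusted p = 0.888), 0.05 (SE 0.30, adjusted p = 0.881) and 0.05 (SE 0.31, adjusted p = 0.884). Variants of miR166 reached 18462 ± 1421 CPM in standard and 2308 ± 466 CPM in HD (log2 fold change −2.67, SE 0.39, adjusted p = 0.00171). Those of miR167, which targets auxin response factors and for which the listed form was under 1% of the reads, were at 10233 ± 908 CPM in HD and 555 ± 91.2 CPM in standard (log2 fold change 4.55, SE 0.36, adjusted p = 0.000457). Variants of the tasiRNA D7 against auxin response factors were at 63.8 ± 4.47 and 9.23 ± 2.27 CPM (adjusted p = 0.000546).

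**Figure D4:**
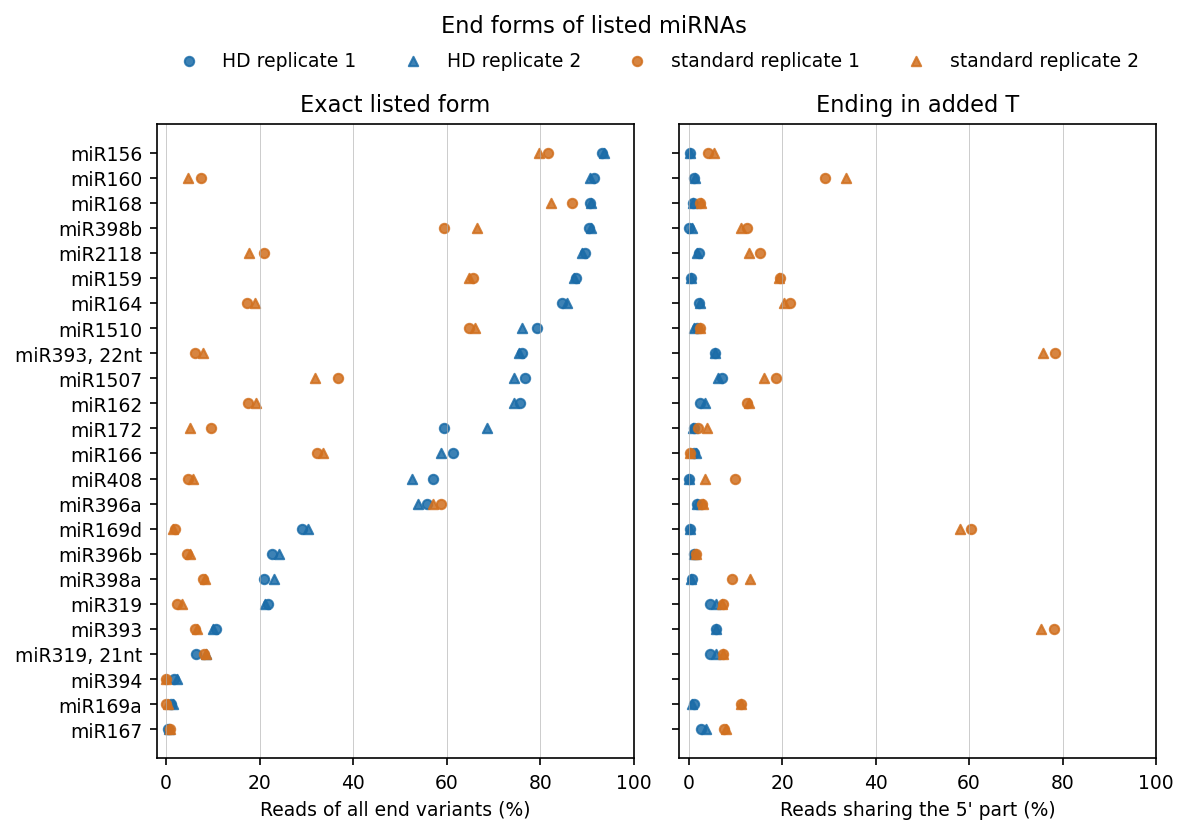
Share (%) of end variants with the exact listed sequence (left) and of reads with added T (right) for 24 listed miRNAs, with a point for each library, and miR394 left out on the right. For miR393 of 22 nt, added T rises from 5.64% in HD to 77.2% in standard libraries.

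Fragments from the 5′ ends of tRNAs went both ways. Those of tRNA Gly-GCC (444 ± 158 CPM in HD and 39.3 ± 14.0 CPM in standard, log2 fold change 3.80, SE 0.47, adjusted p = 0.000990), His-GTG (log2 fold change 3.10), Tyr-GTA (2.37), Asp-GTC (1.69) and Val-AAC (1.19) were higher in HD. Those of tRNA Ala-AGC were higher in standard libraries, at 1767 ± 496 CPM and 192 ± 16.3 CPM in HD (log2 fold change −2.83, SE 0.37, adjusted p = 0.00119). Among RNAs with capped or triphosphate ends, U6 was at 32.1 and 4.65 CPM in the HD libraries and 0.656 and 1.56 CPM in the standard libraries (log2 fold change 2.98, SE 0.90, adjusted p = 0.0244). U3 was at 33.2 ± 5.89 CPM in HD and 86.4 ± 23.6 CPM in standard (log2 fold change −1.01, SE 0.31, adjusted p = 0.0265), and U2 at 8.17 ± 0.0369 and 10.9 ± 0.808 CPM (adjusted p = 0.786). The 8 calls among 9 tested fragments fell to 2 without HD replicate 1, 4 without HD replicate 2, 4 without standard replicate 1 and 5 without standard replicate 2. Calls were lost for Gly-GCC without HD replicate 1 (3.34), Ala-AGC without HD replicate 1 or 2 (both −2.83), Val-AAC without HD replicate 1 (0.97), HD replicate 2 (1.45) or standard replicate 1 (1.03), U6 (4.36 without HD replicate 2) without HD replicate 1 (1.64), standard replicate 1 (2.79) or standard replicate 2 (3.27), and Asp-GTC (1.19 to 2.19) and U3 (−1.10 to −0.66) without any 1 library, for U3 also with median-of-ratios scaling (−0.58), for Asp-GTC for 20 to 24 nt (1.09) and for U6 with a looser filter (2.74). With a stricter filter U3 turned to 0.068, and U2 passed in opposite directions with the stricter filter (0.92) and for 20 to 24 nt (−0.63). U1, 5S rRNA, tRNA Glu-CTC, tRNA Met-CAT and the listed 5.8S start had too few reads to test.

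Lists were also set against all other sequences. All listed miRNAs together stood higher in HD (camera, adjusted p = 0.000465), as did the development miRNAs (adjusted p = 0.00214). Both calls were lost at adjusted p = 0.472 in camera with an estimated correlation. That correlation was 0.0749 for all listed miRNAs and −0.00438 for the development miRNAs, the latter below the preset 0.01. For the development miRNAs the loss thus did not come from correlated members. The triggers of phased siRNAs (adjusted p = 0.108) and the stress miRNAs (adjusted p = 0.122) did not pass. By last base, the 16303 sequences ending in T were lower in HD (median log2 fold change −0.71, adjusted p = 0.00466) and the 19596 ending in A higher (1.03, adjusted p = 0.0197). With an estimated correlation these gave adjusted p = 0.472 and 0.555. Sequences ending in G (0.75, adjusted p = 0.156) and C (0.06, adjusted p = 0.417, with a test leaning to standard libraries) did not pass. These tests count each sequence alike, and shares of reads gave another picture. Reads ending in T were 21.8% in HD and 22.3% in standard. Those ending in C (28.4% and 37.1%) and G (18.6% and 12.7%) differed more. By first base, A (0.99, adjusted p = 0.0621), T (0.70, adjusted p = 0.334), C (−0.45, adjusted p = 0.0793) and G (−0.43, adjusted p = 0.0906) did not pass, though A passed without HD replicate 1 (adjusted p = 0.0410) or 2 (adjusted p = 0.0460), which gave adjusted p = 0.192 and 0.196 with an estimated correlation. A also passed with library size scaling (adjusted p = 0.0489), a looser filter (0.0319), 20 to 24 nt (0.0352) and without adapter-derived reads (0.0415), T with a stricter filter (0.0148), last base G with a stricter filter (0.0329), first base C with a stricter filter (0.0329) and 20 to 24 nt (0.0418), and G with 20 to 24 nt (0.0418). With an estimated correlation these passes were lost, at adjusted p from 0.149 to 0.629, while with a looser filter and an estimated correlation last base T (adjusted p = 0.0256) and first base C (adjusted p = 0.0360) passed, both lower in HD.

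Replicates resembled each other far more than libraries of different adapters. Across the 73259 tested sequences, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.950 between the HD replicates and 0.958 between the standard replicates, and from 0.0965 to 0.127 between adapters. Spearman's rho between adapters was from −0.318 to −0.296, over sequences that had to be frequent in at least 2 libraries, such as those of a single adapter. Replicates of each adapter still differed by more than sampling noise, with a chi-square per degree of freedom of 7.96 in HD and 11.2 in standard libraries.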

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

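Reads outside 18 to 30 nt were used in no comparison of abundance, and they were well above what a count of 0 allows. They made up 5.89% and 8.87% of all reads in HD replicates 1 and 2 and 10.1% and 9.10% in standard replicates 1 and 2. Reads of 31 to 33 nt held 3.89% and 7.75% in HD and 5.04% and 3.51% in standard. By the mean over the 4 libraries, the most abundant was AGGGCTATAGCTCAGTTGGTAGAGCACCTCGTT of 33 nt, at 688 and 2336 reads per 1000000 reads of all lengths in HD and 5126 and 5172 in standard. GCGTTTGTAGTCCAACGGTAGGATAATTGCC of 31 nt went the other way, at 3950 and 4467 in HD, above the former in both HD libraries, and 1058 and 792 in standard. TCTACAGTCCGACGATC, a 17 nt piece of the 5′ adapter, was at 40.97 and 15.2 in HD and 3536 and 5034 in standard. HD adapters would carry degenerate bases after it, so this difference too may follow from adapter design.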

How the results depend on the processing

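Voom weights, the pseudocount of 0.1 and the leaving out of adapter-derived reads were chosen after seeing the data. Leaving out a library leaves a single library in its group, which is then assumed to vary like the other group. Such a fit also has fewer degrees of freedom, so calls can be lost where the log2 fold change hardly moves. That of tRNA Ala-AGC was −2.83 with all libraries and without HD replicate 1 or 2. A call lost in this way therefore need not depend on the library left out. The 63393 sequences called became 147920 (85144 higher in HD, 62776 in standard) with the looser filter, 5357 (2491 and 2866) with the stricter and 40166 (22227 and 17939) for 20 to 24 nt, where other numbers were tested. Those higher in standard numbered 18803 with voom weights and 14074 to 21809 with a library left out. The median log2 fold change of the listed miRNAs was 3.56 with median-of-ratios scaling, 2.46 with the looser and 4.43 with the stricter filter, 2.59 for 20 to 24 nt, 2.14 with end variants summed and 2.67 to 3.20 with a library left out. Scaling moved the median of all sequences from 0.28 to 0.54 (median-of-ratios) or 0.09 (library size). With the stricter filter, scaling factors were 0.610 and 0.606 in HD and 1.62 and 1.665 in standard. Single values then shifted toward HD, such as miR159 from 3.97 to 5.07 and tRNA Ala-AGC from −2.83 to −1.74. Calls of 5′ fragments numbered 4 with voom weights and 2 to 5 with a library left out. Set tests of all listed miRNAs and of last base T gave adjusted p = 0.472 with an estimated correlation, and kept their call otherwise. The difference in the 24 nt share ran from 28.7 to 38.9 percentage points over all its alternatives, and without the 10 most abundant sequences or without adapter-derived reads it kept its direction.

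Direction changed for U2 (0.33 with median-of-ratios scaling, 0.92 with the stricter filter, −0.15 to 0.064 with a library left out) and miR399a (−0.12 with library size scaling, −0.11 with the looser filter, −0.29 for 20 to 24 nt, −0.12 to 0.20 with a library left out), neither called with the settings of the report, though U2 passed with the stricter filter and, at −0.63, for 20 to 24 nt. It changed with the stricter filter for U3 (0.068), GGAATGTTGTCTGGCTCGAGG (0.050) and the set of first base A (adjusted p = 0.935). Without sequences read once, the difference turned to 0.0686 percentage points for 21 nt and −0.984 for first base A, and it was −0.578 for first base T over distinct sequences. The other 170 of 173 alternatives for shares and complexity kept their direction. Of 806 values of single small RNAs, 715 kept direction and call, 67 lost the call and 13 gained it. Voom weights ended the calls of miR393, miR396a, U3, U6, Asp-GTC and Val-AAC, and the pseudocount of 0.1 those of miR396a and of the summed 5.8S reads, whose call was also lost without standard replicate 1 (−2.89) or 2 (−3.07). The cause of these changes was not tested. Replicates correlated at a mean Pearson's r of 0.966 for sequences of at least 10 CPM and 0.954 for all, and libraries of different adapters at −0.0146 for the former.

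With the replicate number as a block, 65878 sequences and 27 listed miRNAs were called. The prior degrees of freedom of that fit were infinite, against 3.15 without the block. Each sequence was thus tested with the variance of the intensity trend and not its own. Calls added by the block are therefore no evidence that libraries of equal number are paired. Replicate 1 minus replicate 2 correlated at 0.154 between the adapters over 2 pairs, which cannot decide whether libraries of equal number share RNA. The block added the calls of the phased siRNA triggers (adjusted p = 0.0224) and stress miRNAs (adjusted p = 0.0468), both lost at adjusted p = 0.677 with an estimated correlation. With the preset correlation, adjusted p over the alternatives ran from 0.0224 to 0.231 and from 0.0468 to 0.373, and the triggers also passed with the looser filter (adjusted p = 0.0366, and 0.196 with an estimated correlation). The count models and the genome-matched share were not run. Depth limits items such as miR399a, read 7 to 12 times per library.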

Other observations

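The tests by end-base mix of the 24 nt share and by totals without adapter and ribosomal reads were chosen after the result was seen, and so were the bounds for summed end variants, whose sum was among the alternatives chosen earlier. Also chosen afterwards were the sequences and ends described next. The labels give no biological difference between the groups, so no biological explanation was tested.

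Pairs of sequences with an overhang of 2 nt at both 3′ ends, a mark of Dicer products, were counted beside overhangs from −4 to 4 nt. Among sequences of 24 nt, with 1356072 reads drawn from each library, 4.31 ± 0.0630% in HD and 3.01 ± 0.142% in standard had a partner with that overhang, and 3.27% to 3.99% and 1.75% to 2.63% had one with another overhang. For 21 nt, with 1229695 reads drawn, these were 7.31 ± 0.109% and 2.52 ± 0.207%, and for other overhangs 5.503% to 6.79% and 1.13% to 2.41%. For 22 nt, HD libraries had the highest share at 2 nt (3.69 ± 0.167%), and standard libraries at 3 nt (1.80 ± 0.0579%, with 1.44 ± 0.0476% at 2 nt). Sequences were also grouped by their 3 end bases, with adapter-derived ones left out, and the extremes are given with no test. Of 2877 sequences ending in CCT, 10.3% were higher in HD (median log2 fold change −1.22), and of 2658 ending in CGA, 82.1% (1.34). At the 5′ end, medians ran from −0.96 for GGG to 1.28 for ACT. AGCCTATGATGATAAAACATATC, the 19 nt sequence most raised in HD with 4 more bases, had 290 and 261 reads in the standard libraries and none in HD. GGCGGATGTAGCCAAGTGGATCAAG was at 1086 CPM in HD replicate 1 and 16910 CPM in HD replicate 2, a ratio of 15.6, and at 19.4 and 21.2 CPM in the standard libraries.

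The lower share of 24 nt reads in standard libraries was set against 3 technical explanations. Reweighting the standard libraries to the HD mix of the first 2 and last 2 bases gave a share of 15.9%, far below the 47.2% of HD, which argues against the end-base mix as the whole cause. If pieces of broken RNA could be ligated, breakage would leave more miRNAs without their 5′ bases in standard libraries. Over 17 miRNAs the ratio, standard to HD, of the share of reads that had lost 5′ bases had a median of 0.312. That for 3′ bases had a median of 2.13. Whether broken pieces carry 5′ ends that an adapter can join is not known here, so this test cannot decide about breakage. Shorter 3′ forms of the same small RNAs stay open. For this, 867 starts of 18 bases were taken from 24 nt sequences of at least 10 CPM in HD replicate 1. Whether these sequences are siRNAs was not checked. Of the starts, 491 had at least 20 reads in each other library. For these the median share of 24 nt was 52.7% and 52.0% in standard libraries and 86.3% in HD replicate 2. The ratio was 0.606, between the bounds set for either answer. This ratio also falls with longer forms. Over all reads of the 491 starts, 24 nt held 19.4% in HD replicate 2 and 7.63% in standard libraries. Reads of 25 nt (5.72% and 11.5%) and 26 nt (4.10% and 10.9%) rose. Reads of 20 nt (3.83% and 5.84%) rose less, and those of 21 nt (35.7% and 33.7%) did not. Reads of 29 nt (2.34% and 1.61%) and 30 nt (7.21% and 2.57%) fell. The pool is weighted to the starts with most reads. In HD replicate 2, 24 nt held 19.4% of it, against a median of 86.3% per start. The pooled lengths therefore cannot show which forms took the place of 24 nt in most of the 491 starts. Median total reads of these starts were 0.310 and 0.287 times those of HD replicate 2 (0.147 and 0.130 over all 867), but the starts were picked because their 24 nt form was frequent in HD, so these values set no limit on how much of the loss is due to shortening.

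The higher level of listed miRNAs in HD was also set against 3 explanations. Scaled by totals without adapter-derived and 5.8S reads, their median log2 fold change was 2.65, against 2.81 with library size scaling. Those classes held 4.67% and 8.04% of standard reads, too few to remove such a difference. Reads taken up by them therefore do not account for it. Against sequences of the same length, first and last base, their median was still 2.41 higher, which argues against end bases alone. With all end variants of the same miRNAs summed it was 2.14, so other end forms may account for part of the difference, and for miR162, miR393 and miR408 for nearly all of it. A preference of each adapter for particular whole sequences stays open and was not tested apart from folding.

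Whether folding of a small RNA with an adapter goes with the difference was tested on 2000 sequences drawn from those tested. The energy change on joining an adapter is more negative where more pairing is gained. Spearman's rho between log2 fold change and this energy change was 0.0576 for the 5′ adapter, inside the range of 39 shuffled adapters (−0.0307 to 0.139). For the 3′ adapter rho was −0.131, just outside their range (−0.113 to 0.120), so sequences that pair more with it were slightly lower in the standard libraries. Both adapters were tested without adjustment, with only 39 shuffles each and on sequences that are not independent. A value just outside the range is weak evidence, so whether folding with the 3′ adapter contributes stays open. The adapter sequences are those generally used for Illumina small RNA kits and are not given in the sources used here.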
